A study of Mus musculus with 46 samples.

How the data were processed

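Hearts of male C57BL/6J and MRL/MpJ mice, 15 to 20 weeks old, were taken on day 0 without surgery or on day 1 or day 5 after ligation of the left coronary artery, per the labels. Infarct and noninfarct regions of the left ventricle were separated with a biopsy punch and frozen, and total RNA of each was labelled with biotin and hybridized to an Affymetrix MOE430A array. The series holds 46 arrays in 12 groups of strain, day and region, 4 arrays per group and 3 in the C57 day 0 groups, each called a biological replicate by the labels. The labels do not say which infarct and noninfarct arrays share a heart. The cells of the tissue were not sorted, so a change of a gene in a region holds changes of its cells and of their shares.

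The deposited values are intensity values per probe set on a linear scale, background corrected, normalized and summarised by the authors with GCRMA per the submitters' processing notes, which give no version. The design of the comparisons, written before the data were examined, assumed log2 values and foresaw linear ones: the table turned out linear, and log2 was taken with no pseudocount, the smallest value being 1.03. Array medians lay between 18.6 and 22.4 and the 75th percentiles between 106.2 and 138.1. No detection calls were used. Of 340 named genes by comparison 136 had a group mean below the median of every array, and the size of such a change is not exact. Of 22690 probe sets, 64 Affymetrix controls were left out. A probe set counted for a gene if the platform's table gave it exactly 1 symbol, which 20380 did for 12393 genes, while 691 had several symbols and 1555 none. Symbols were matched to RefSeq gene records by Entrez ID for 20351 of them, and 0 changed. Some items of the files are not reported here.

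Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the tested probe sets), with a call at an adjusted p under 0.05. Changes after infarction, the course from day 1 to day 5, differences between strains and the test of strain by infarction (the difference of the changes) were fitted within a region on its 23 arrays, with 1 mean per group. Differences between regions were fitted on all 46 arrays. In all, 26 comparisons were made. A probe set was tested if its value lay above the median of its array in at least 3 arrays of the fit, a filter that does not use the groups: 12834 probe sets passed in infarct tissue, 12344 in noninfarct tissue and 13138 over both. Comparisons with the same day 0 arrays share the chance deviations of those arrays.

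A gene was represented by its probe set with the highest mean over all arrays among those that passed. The genes named for a comparison follow a rule fixed in advance: the 5 largest rises and the 5 largest falls among called genes whose groups do not overlap (no overlap rule for strain by infarction), up to 4 called members with the largest changes per gene list described, and 15 index genes. Clone-like symbols were passed over, and members that were not called are given as values. Fixed before the data were examined, the gene lists cover sarcomere and calcium handling, fetal and stress cardiac genes, fatty acid oxidation, oxidative phosphorylation, glycolysis and hypoxia response, heat shock and endoplasmic reticulum stress, cytokines and adhesion molecules, complement, MHC and antigen presentation, interferon response, collagens and matrix proteins, matrix proteases and inhibitors, growth factors, cell cycle, and cell cycle inhibitors and p53 targets. Other lists hold markers of neutrophils, monocytes and macrophages, T lymphocytes, B lymphocytes, mast cells, fibroblasts and epicardium, smooth muscle and myofibroblasts, endothelium, erythroid cells and platelets, adipose tissue, nerve and Schwann cells, atrium and conduction system, and skeletal muscle. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, two-sided, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. Of 572 list tests 247 were called with the preset and 37 with the estimated correlation. Quantile normalization or centring turned the sign of 0 list medians.

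Strain differences shared by the 3 days were counted as probe sets called in the same direction on each, beside the product of the shares of calls. Chance was weighed by rearranging the labels of the arrays of the 2 groups compared, 35 ways for most comparisons and 100 random ways for strain by infarction. The numbers of replicates were checked for pairing of hearts across regions: same-numbered infarct and noninfarct arrays had deviations from their group means correlated above 0.1 across probe sets in all pairs of C57 day 0 (0.23 to 0.43) and MRL day 1 (0.34 to 0.56), but not of the other groups (MRL day 0 from 0.07 to 0.55). The pairing comes from the data, not the labels, and the replicate number as a block was an alternative.

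Alternatives fixed in advance were no filter, a filter at the 75th percentile of the array in place of the median, quantile normalization, arrays centred on their median, an offset of 32 added before the log2, an intensity trend with a robust prior, array weights, a replicate block, all 46 arrays in one fit, only the groups compared, each array left out in turn, an adjusted p under 0.01, fry, the mean of all probe sets of a gene, and the estimated correlation. Chosen after seeing the data were the fits without the libraries labelled C57 day 5 noninfarct replicate 3 and MRL day 5 infarct replicate 3, the arrays left out in turn for the list tests and the shared strain differences, and the block for the latter. The main fits keep every array in the group of its label.

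The fits were tested on simulated data with the spread and number of arrays of the series. At log2 changes of 1 and 2, calls were made for 25 and 86 of 100 changed probe sets for C57 infarct day 1, 61 and 96 for C57 noninfarct day 1, 41 and 87 for the strains in infarct tissue at day 0, 12 and 77 for strain by infarction in infarct tissue at day 5, and 64 and 92 for the MRL regions at day 1. Calls among 12634, 12144, 12634, 12634 and 12938 unchanged ones numbered 8, 7, 10, 4 and 9. The number of arrays limits the precision. RNA quality was read from the 3' minus 5' log2 differences of the Gapdh and Actb controls. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.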

Results

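The series measured RNA from the left ventricle of C57BL/6J (C57) and MRL/MpJ (MRL) mice before and 1 and 5 days after ligation of the left coronary artery, in the infarct region and in the noninfarct region. The comparisons address how heart tissue changes after infarction, whether the strains differ before it, and whether they respond to it differently. Each group had 4 arrays, except the C57 day 0 groups, which had 3. At day 0 no ligation was done, and "infarct" there names the matching anterior-apical region of an unoperated heart. Changes are differences of group means of log2 intensity, written as log2 change ± SE, and a gene was called with a limma adjusted p under 0.05. In lists of genes, the adjusted p stands in parentheses after the change. For gene lists fixed before the data were examined, the count of called members is given with the count adjusted over the list alone and the adjusted p of the list test with an estimated correlation. The first principal component of all tested probe sets held 52.7% of the variance. A pair of day 5 libraries stood apart from their groups: the library labelled C57 day 5 noninfarct replicate 3 lay at 99.1 on the first component (the other three of its group at -30.2, 21.8 and 35.3) and at 13.7 on the third (-24.1, -20.2 and -22.1). The library labelled MRL day 5 infarct replicate 3 lay at 11 on the first (107.9, 115.7 and 109) and at -21.2 on the third (11.8, 12.8 and 11.8). C57 day 5 infarct replicate 1 lay at 40.5 on the first (117.2, 98.8 and 113). All arrays kept the groups of their labels, and values without the pair stand beside many results that it moves.

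**Figure D1:**
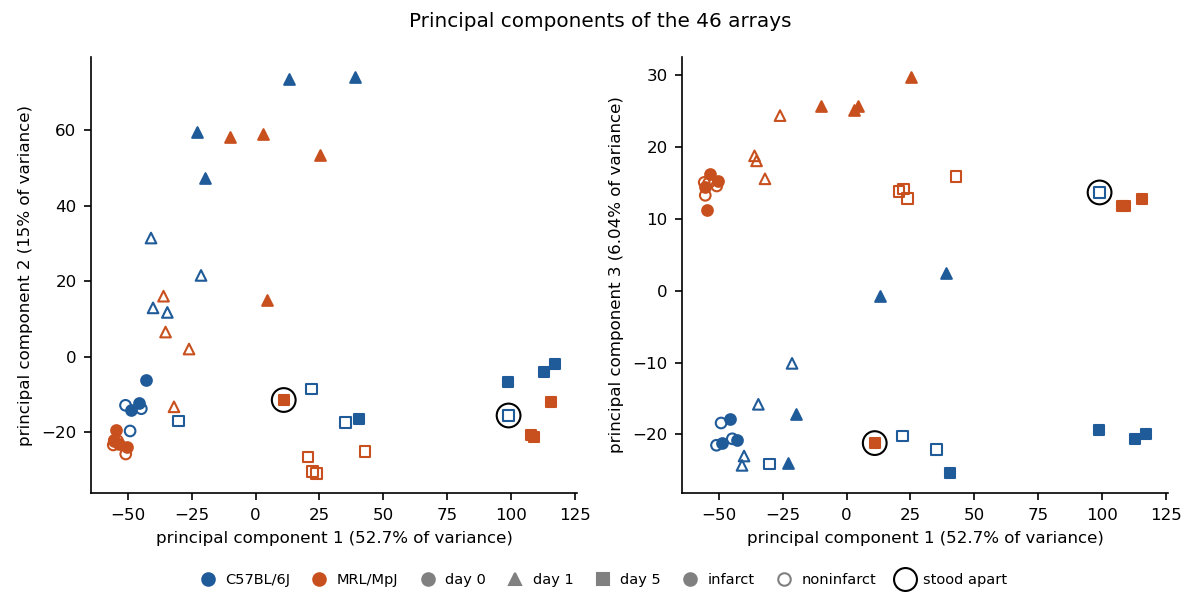
Each point is 1 of the 46 arrays, placed by principal component 1 against 2 (left) and 1 against 3 (right) of the log2 intensities, in the unit of the component scores, with color and marker for strain, day and region. Day 0 arrays lie between -55.8 and -43.1 on component 1, and the libraries labelled C57 day 5 noninfarct replicate 3 (99.1) and MRL day 5 infarct replicate 3 (11) lie away from their groups.

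Infarct tissue of both strains at day 1 was marked by neutrophil, cytokine and cardiac stress genes. The neutrophil genes Lcn2, S100a9 and S100a8 and the protease inhibitor Timp1 were among the 5 largest rises in both strains. In C57 the log2 changes were 8.20 ± 0.36 for Lcn2 (4.1e-12), 7.63 ± 0.53 for S100a9 (9.2e-09), 7.47 ± 0.48 for S100a8 (3.5e-09), 7.32 ± 0.60 for Timp1 (1e-07) and 6.93 ± 0.96 for the chemokine Cxcl2 (4.8e-05). In MRL they were 8.33 ± 0.56 for Timp1 (3.9e-09), 6.84 ± 0.49 for S100a9 (1.1e-08), 6.65 ± 0.44 for S100a8 (3.9e-09), 6.49 ± 0.55 for Prg4 (1.1e-07) and 6.44 ± 0.33 for Lcn2 (1.1e-10). The largest falls in C57 were Asb10 (-4.04 ± 0.94), the clock-controlled Dbp (-3.71 ± 0.71), Cenpf (-3.46 ± 0.48), Dnajc28 (-3.12 ± 0.62) and Msrb2 (-2.96 ± 0.67). Adjusted p ranged from 5.5e-05 to 0.006. In MRL they were Cenpf (-3.49 ± 0.45), Asb15 (-3.22 ± 0.34), Ttll1 (-3.20 ± 0.80), Cacnb2 (-3.07 ± 0.77) and Efnb3 (-2.86 ± 0.95). Their adjusted p lay between 2e-06 and 0.037. At day 0 the means of Timp1 (2.71 in C57, 2.13 in MRL), S100a8 (3.31, 3.31) and Lcn2 (2.70, 2.84) lay below the median of every array (4.22 to 4.48), so the sizes of their rises are not exact. With an offset of 32 they were 4.83 and 5.32 for Timp1, 5.41 and 4.62 for S100a8 and 5.65 and 4.06 for Lcn2. Of 12834 probe sets, 1995 were called in C57 (1205 higher, 790 lower) and 2760 in MRL (1340 higher, 1420 lower; 1535 and 1192 centred). The strains shared 812 higher and 501 lower, where chance would give 126 and 87.4, and none was called in opposite directions. Without the libraries that stood apart these were 994 and 830 (chance 180 and 182), with 1 opposite. C57 then had 1460 higher and 1207 lower. The C57 count was 1324, 1181 and 1253 without day 0 replicates 1, 2 and 3. The MRL count was 1833 without day 0 replicate 1 and 1612 without day 1 replicate 2. The call of Efnb3 ended without any MRL day 0 replicate or MRL day 1 replicates 2 or 4 (adjusted p 0.063 to 0.16).

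Among the lists, 14 of 19 cytokine and adhesion genes rose in C57 (15 adjusted over the list alone) and 15 of 19 in MRL (17 over the list alone), with median log2 changes of 3.68 and 3.66. They included Cxcl1 (5.84 ± 0.86 in C57, 4.75 ± 0.79 in MRL), Socs3 (5.15 ± 0.56, 4.74 ± 0.52) and Il6 (4.91 ± 1.10, 3.99 ± 1.02). Of 7 neutrophil markers 5 rose in C57 and 6 in MRL (7 and 6 adjusted over the list alone). Of 8 fetal and stress cardiac genes 6 and 7 rose (7 and 7 over the list alone), led by Fhl1 (2.68 ± 0.26, 2.63 ± 0.24), Xirp1 (2.54 ± 0.35, 2.09 ± 0.32) and Rcan1 (2.53 ± 0.47, 2.27 ± 0.43). Of 14 heat shock and endoplasmic reticulum stress genes 9 rose in each strain (in C57 11 higher and 1 lower over the list alone, in MRL 9 higher and 1 lower). Risers included the chaperone genes Hspa1a (6.69 ± 0.92, 5.02 ± 0.85) and Hspb1 (2.17 ± 0.23, 2.10 ± 0.22). The tests of these 4 lists kept an adjusted p of at most 0.036 in C57 and 0.029 in MRL with an estimated correlation.

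Other lists were called with the preset correlation alone. Of 23 monocyte and macrophage markers 7 rose in C57 and 12 in MRL (9 and 13 over the list alone; adjusted p = 0.68 and 0.31 with an estimated correlation). Their median change differed among arrays, at 0.16, 0.23, 2.91 and 1.85 in C57 replicates 1 to 4 and 1.91, 2.66, 0.19 and 1.23 in MRL. Risers included Arg1 (6.02 ± 1.29, 5.09 ± 1.20), Cd14 (5.45 ± 0.63, 4.46 ± 0.59) and Lgals3 (5.16 ± 0.91, 6.00 ± 0.84). Of 33 collagens and matrix proteins 10 rose and 2 fell in C57 (11 and 3 over the list alone; adjusted p = 0.68 with an estimated correlation) and 11 rose and 2 fell in MRL (13 and 2; 0.34). Risers were the wound matrix genes Thbs1 (5.54 ± 0.58, 4.37 ± 0.54), Tnc (4.47 ± 0.61, 6.08 ± 0.56), Ccn2 (3.92 ± 0.27, 3.21 ± 0.25) and the crosslinking enzyme Lox (3.86 ± 0.43, 3.13 ± 0.39). The fibrillar collagens Col1a1 (-0.19 in C57, adjusted p 0.83; 0.75 in MRL, adjusted p 0.2) and Col3a1 (-0.51, 0.04) were not called. Hbegf (5.13 ± 0.53, 4.44 ± 0.49) and Tgfb2 (3.75 ± 0.40, 3.09 ± 0.37) rose among growth factor genes. In this list 6 of 19 rose in C57 and 8 in MRL (6 and 9 over the list alone, 1 member falling in C57; adjusted p = 0.18 and 0.076 with an estimated correlation). Of 16 glycolysis and hypoxia genes 8 rose in C57, and 6 rose and 1 fell in MRL (9, and 6 and 1, over the list alone; adjusted p = 0.074 and 0.31 with an estimated correlation). Examples are Hmox1 (5.21 ± 0.74, 5.12 ± 0.69), the glucose transporter Slc2a1 (3.86 ± 0.41, 3.31 ± 0.38) and Adm (3.37 ± 0.43, 3.09 ± 0.39). Of 22 matrix proteases and inhibitors 8 rose in each strain and 1 fell in MRL (in C57 9 and 1, in MRL 8 and 1, over the list alone; adjusted p = 0.22 and 0.31 with an estimated correlation). Adamts4 (3.99 ± 0.49, 4.45 ± 0.46) and Mmp14 (3.53 ± 0.54, 2.90 ± 0.50) were among the risers. Of 20 fatty acid oxidation genes 1 rose in C57 (0 over the list alone; median -0.60) and 5 fell in MRL (5 over the list alone; median -0.73; adjusted p = 0.69 with an estimated correlation). Of 22 oxidative phosphorylation genes 1 fell in MRL and none was called in C57 (0 in each over the list alone; medians -0.53 and -0.59; adjusted p = 0.73 and 0.69 with an estimated correlation). The 3' minus 5' Gapdh log2 difference, a marker of RNA quality, averaged 0.01 in C57 day 1 infarct tissue (-0.19 to 0.41, highest in replicate 4) and -0.03 in MRL (-0.26 to 0.38, highest in replicate 3), against -0.18 (-0.22 to -0.14) and -0.25 (-0.28 to -0.18) at day 0.

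Index genes of the heart muscle followed a time course in infarct tissue. Nppb (B-type natriuretic peptide) rose at day 1 by 2.17 ± 0.38 in C57 (adjusted p 0.00063) and 3.35 ± 0.35 in MRL (2.2e-06), from group means of 10.95 and 9.86. Nppa (atrial natriuretic peptide) rose at day 1 by 1.35 ± 0.45 in C57 (adjusted p 0.045) and 1.74 ± 0.41 in MRL (0.0061), and in both strains at day 5 (2.43 ± 0.45 in C57, 2.31 ± 0.41 in MRL). The cell cycle inhibitor Cdkn1a rose at day 1 by 4.04 ± 0.43 in C57 (2.4e-06) and 2.40 ± 0.40 in MRL (0.00033), and the monocyte attractant Ccl2 by 4.36 ± 0.58 (3.1e-05) and 4.44 ± 0.53 (1e-05). The alpha myosin heavy chain gene Myh6 (-0.43, -0.18), the calcium pump gene Atp2a2 (-0.34, -0.12), Acta2 (0.06, 0.50) and Mki67 (-0.16, 0.50) were not called at day 1. Neither was the beta myosin gene Myh7 (2.44, adjusted p 0.062; 1.56, adjusted p 0.17). At day 5 Myh6 fell (-1.15 ± 0.37 in C57, -1.26 ± 0.34 in MRL), as did Atp2a2 (-0.77 ± 0.26, -0.76 ± 0.24), while Nppb stayed above day 0 (0.97 ± 0.38, adjusted p 0.046; 1.69 ± 0.35, adjusted p 0.00073). The C57 call of Nppa at day 1 ended without any day 0 replicate or day 1 replicates 3 or 4 (adjusted p 0.066 to 0.18). It also ended with no filter (0.088) and with arrays centred (0.051). The C57 call of Nppb at day 5 ended without any 1 of its 7 arrays (0.053 to 0.13) and with no filter (0.076). It also ended with arrays centred (0.11) and with all 46 arrays in one fit (0.052). Likewise, the calls of Myh6 in C57 ended without day 0 replicate 1 or day 5 replicates 2 or 4 (adjusted p 0.05 to 0.057). Those of Atp2a2 ended without day 0 replicates 1 or 3 or day 5 replicates 2 or 4 (0.051 to 0.078). In MRL the call of Atp2a2 ended without MRL day 5 infarct replicate 2 (0.068), and after quantile normalization those of Myh6 (-0.68, 0.11) and Atp2a2 (-0.57, 0.064) in C57 ended.

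**Figure D2:**
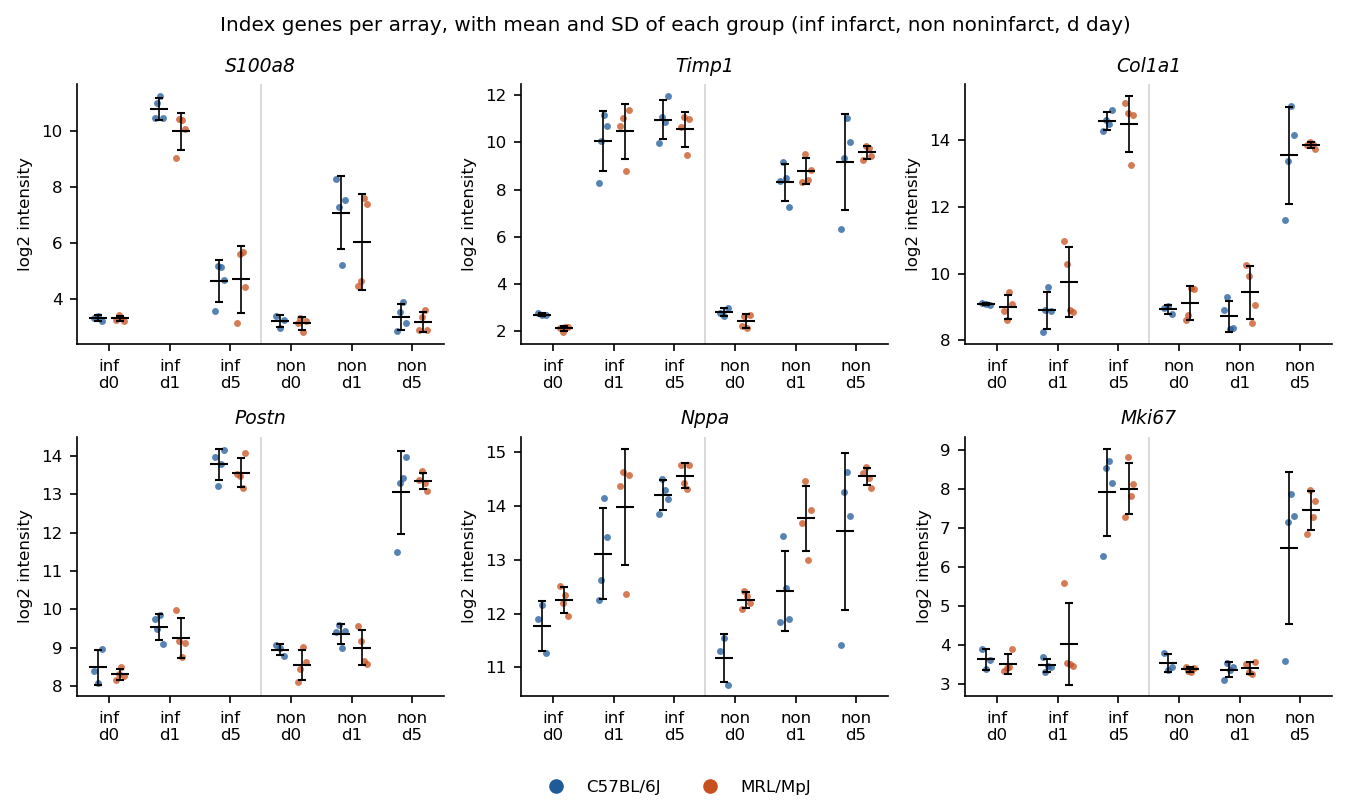
Log2 intensity (vertical axis) of index genes in each array (points, colored by strain), by day and region, with the mean (dash) and SD (bar) of each group of 4 arrays, or 3 in the C57 day 0 groups. Timp1 went from group means of 2.71 and 2.13 in C57 and MRL infarct tissue at day 0 to 10.04 and 10.46 at day 1, while Col1a1 stood at 8.90 and 9.76 at day 1 and at 14.58 and 14.49 at day 5.

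Infarct tissue at day 5 held more Lgals3, Timp1, Sprr1a and Tnc and less Kcnip2, Yipf7 and Efnb3 than at day 0 in both strains. In C57 the largest rises were the macrophage gene Lgals3 (8.72 ± 0.91), Timp1 (8.24 ± 0.60), Lox (8.07 ± 0.43), Sprr1a (7.85 ± 0.75) and Tnc (7.47 ± 0.61). These had adjusted p of 1.7e-10 to 7.1e-07. In MRL they were Lgals3 (8.95 ± 0.84), Timp1 (8.42 ± 0.56), Sprr1a (7.42 ± 0.69), Sfrp2 (7.13 ± 0.50) and Tnc (6.98 ± 0.56). The adjusted p of these genes ran from 2.1e-09 to 1.3e-07. The largest falls were Rpl3l (-4.82 ± 0.93), Kcnip2 (-4.29 ± 0.96), Yipf7 (-3.88 ± 0.96), Efnb3 (-3.78 ± 1.03) and Fitm1 (-3.78 ± 0.97) in C57 (adjusted p 5e-04 to 0.006). In MRL they were Ift81 (-4.88 ± 0.63), Efnb3 (-4.80 ± 0.95), Thrsp (-4.75 ± 0.72), Kcnip2 (-4.71 ± 0.89) and Yipf7 (-4.63 ± 0.89; adjusted p 5.8e-06 to 0.00045). Calls numbered 5480 in C57 (3005 higher, 2475 lower; 2639 higher and 3268 lower after quantile normalization, 2390 and 3553 with arrays centred on their median) and 6022 in MRL (3025 higher, 2997 lower; 2874 and 3445, and 2759 and 3422). The median probe set of C57 moved by -0.14 with quantile normalization and by -0.21 with centring. Without the libraries that stood apart 5863 and 6754 were called, and 5474 and 5887 kept their call and direction. Strains shared 2459 higher and 2075 lower probe sets, where chance would give 708 and 578, and 2 were called in opposite directions. Rearranged labels of the C57 arrays called up to 5632, so chance was not excluded for the C57 count.

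All 33 collagens and matrix proteins rose at day 5 in both strains (33 adjusted over the list alone; median log2 change 3.29 and 3.32; adjusted p = 0.086 in C57 and 0.091 in MRL with an estimated correlation). Among them were Col1a1 (5.49 ± 0.45, 5.48 ± 0.42) and fibronectin Fn1 (5.89 ± 0.59, 6.33 ± 0.54). Macrophage markers rose in 21 of 23 in each strain (21 over the list alone; medians 3.66 and 3.64; adjusted p = 0.18 and 0.16 with an estimated correlation). They included Gpnmb (7.44 ± 1.07, 6.91 ± 0.99) and Cd68 (6.18 ± 0.78, 6.08 ± 0.72). Of 24 cell cycle genes 18 rose in C57 and 20 in MRL (19 and 20 over the list alone; adjusted p = 0.18 and 0.16 with an estimated correlation). Risers were, among others, Top2a (5.22 ± 0.57, 5.28 ± 0.53) and the proliferation marker Mki67 (4.27 ± 0.51, 4.49 ± 0.47). Fibroblast and epicardial markers rose in 7 of 9 in each strain (7 over the list alone), among them Fap (3.79 ± 0.55, 4.07 ± 0.51). Smooth muscle and myofibroblast markers rose in 7 and 8 of 11 (7 and 8 over the list alone, 1 member falling in C57), such as Tagln (3.53 ± 0.45, 3.20 ± 0.42). These lists had adjusted p = 0.18 and 0.093, and 0.22 and 0.21, with an estimated correlation. Proteases such as Mmp14 (6.08 ± 0.54, 5.64 ± 0.50) rose in 14 and 16 of 22 (14 and 16 over the list alone; adjusted p = 0.18 and 0.16 with an estimated correlation). Of 13 interferon response genes 11 rose in C57 and 8 in MRL (12 and 10 over the list alone; 6 in MRL without the libraries that stood apart; adjusted p = 0.18 and 0.29 with an estimated correlation). Bst2 was among them (2.95 ± 0.59, 3.79 ± 0.55). Of 10 MHC and antigen presentation genes 9 and 8 rose (9 and 8 over the list alone; adjusted p = 0.18 and 0.093 with an estimated correlation), including H2-Aa (2.33 ± 0.64, 4.55 ± 0.59) and Cd74 (2.24 ± 0.55, 3.46 ± 0.51). Complement genes such as C3ar1 (5.67 ± 0.81, 5.55 ± 0.75) rose in 4 and 6 of 7 (6 and 6 over the list alone; adjusted p = 0.18 for each with an estimated correlation).

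Fatty acid oxidation genes fell in 18 of 20 in C57 and in all 20 in MRL (18 and 20 adjusted over the list alone; median log2 change -1.96 and -2.10; adjusted p = 0.23 and 0.24 with an estimated correlation). Examples are Eci1 (-2.83 ± 0.62, -3.06 ± 0.58) and Cpt2 (-2.49 ± 0.52, -2.59 ± 0.48). All 22 oxidative phosphorylation genes fell in both strains (22 over the list alone; medians -1.54 and -1.46; adjusted p = 0.23 and 0.28 with an estimated correlation). They included Cox7a1 (-2.56 ± 0.60, -2.72 ± 0.56) and Ndufs1 (-1.94 ± 0.50, -2.45 ± 0.46). Of 22 sarcomere and calcium handling genes 15 fell in C57 and 17 in MRL (over the list alone 16 fell and 1 rose, and 18 fell; adjusted p = 0.29 and 0.32 with an estimated correlation). Those that fell included the Z-disc genes Tcap (-3.21 ± 0.67, -2.86 ± 0.62) and Ldb3 (-2.47 ± 0.54, -2.47 ± 0.50). In C57 replicate 1 the medians were -0.84 for fatty acid oxidation (other three -2.42 to -2.02), -0.63 for oxidative phosphorylation (-2.06 to -1.57) and -0.36 for sarcomere genes (-1.49 to -0.9). Among 15 endothelial markers 1 rose and 2 fell in C57 and 2 rose and 2 fell in MRL (1 and 2 in each over the list alone), such as Flt1 in MRL (-0.92 ± 0.24). Gapdh 3' minus 5' log2 differences averaged 0.21 (SD 0.36) in C57 day 5 infarct tissue, with 0.73 in replicate 2, and -0.09 (SD 0.06) in MRL.

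**Figure D3:**
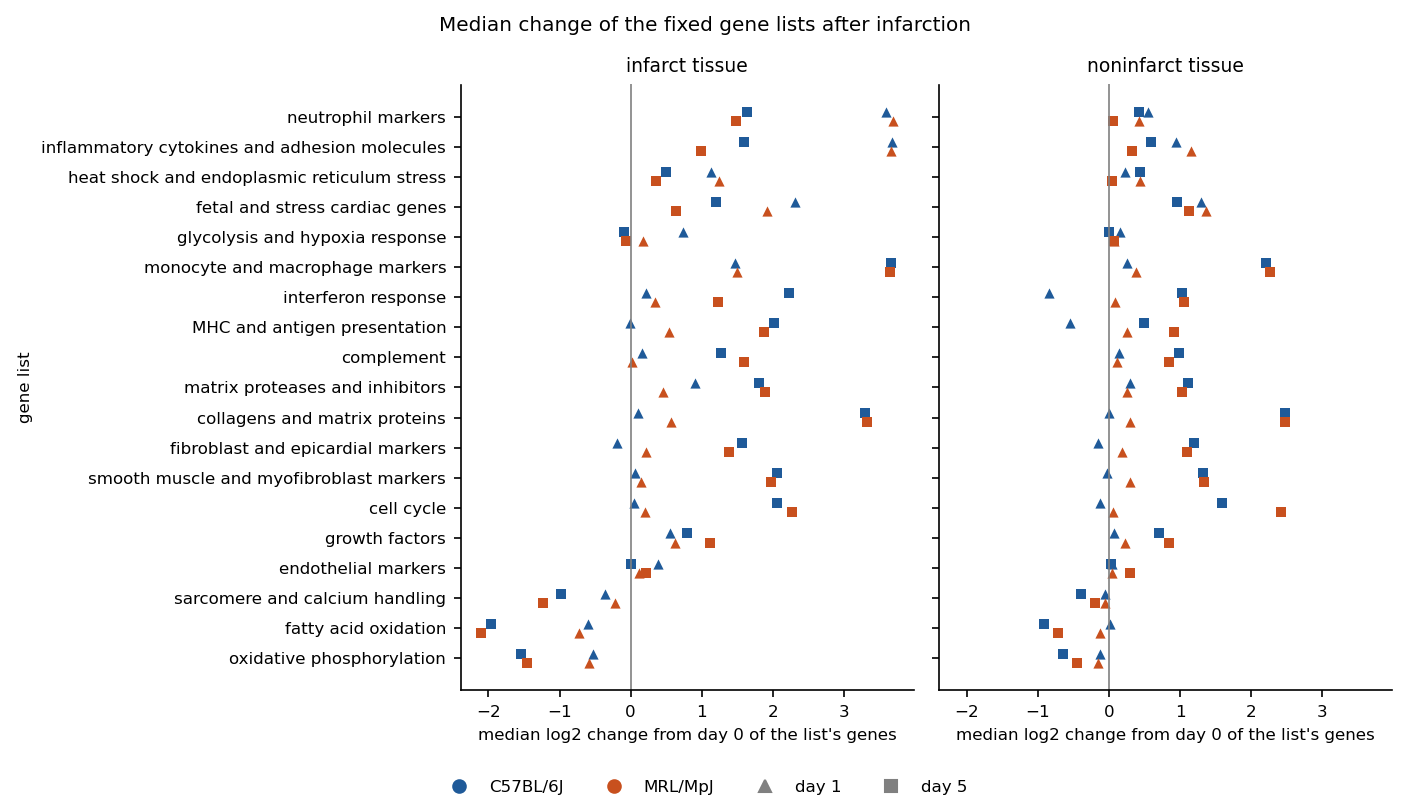
Median log2 change from day 0 (horizontal axis) of the genes of each fixed list (vertical axis) in infarct (left) and noninfarct (right) tissue, with points for each strain (color) and day (marker). Collagens and matrix proteins stand at 0.10 and 0.57 at day 1 and at 3.29 and 3.32 at day 5 in infarct tissue, and fatty acid oxidation at -1.96 and -2.10 at day 5.

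From day 1 to day 5, matrix genes of infarct tissue rose and neutrophil markers fell. The secreted matrix genes Mfap4 (6.99 ± 0.46 in C57, 7.20 ± 0.46 in MRL), Sfrp2 (7.41 ± 0.50, 7.11 ± 0.50) and Ltbp2 (6.63 ± 0.48, 5.69 ± 0.48) and the macrophage genes Gpnmb (7.51 ± 0.99, 6.68 ± 0.99) and Ms4a7 (7.15 ± 0.65, 5.75 ± 0.65) had the largest rises in both strains. The adjusted p was at most 5.9e-05. Cxcl2 (-6.75 ± 0.89, -4.92 ± 0.89), Lcn2 (-6.56 ± 0.33, -4.96 ± 0.33), S100a8 (-6.13 ± 0.44, -5.26 ± 0.44) and S100a9 (-5.83 ± 0.49, -5.95 ± 0.49) fell most in both, beside Hspa1a in C57 (-6.37 ± 0.85) and Ankrd2 in MRL (-6.10 ± 0.37). All had adjusted p of at most 0.00043. Of 33 matrix genes 29 rose in each strain (29 adjusted over the list alone; adjusted p = 0.048 for each with an estimated correlation), and of 7 neutrophil markers 5 fell in C57 and 4 in MRL (5 and 4; 0.034 and 0.048). Macrophage markers rose in 17 of 23 in C57 and 15 in MRL (17 and 16 over the list alone, 1 member falling in MRL; adjusted p = 0.21 and 0.25 with an estimated correlation). Of 8 fetal and stress genes 4 fell and 2 rose in C57 and 4 fell in MRL (4 and 2, and 6, over the list alone; adjusted p = 0.29 and 0.13 with an estimated correlation). Heat shock genes fell in 9 of 14 in each (10 over the list alone; adjusted p = 0.062 and 0.057 with an estimated correlation). Cytokine genes fell in 12 and 13 of 19, 1 rising in each (12 and 14 fell and 1 rose over the list alone; adjusted p = 0.21 and 0.13 with an estimated correlation). Fatty acid oxidation genes fell in 16 and 14 of 20 (19 and 18 over the list alone; adjusted p = 0.26 and 0.25 with an estimated correlation), while MHC genes rose in 8 of 10 in each (9 and 8; 0.048 and 0.09). Col1a1 rose by 5.68 ± 0.42 in C57 (6.9e-09) and 4.72 ± 0.42 in MRL (1.1e-07). Calls numbered 4394 in C57 (2378 higher, 2016 lower; 1955 and 2932 with arrays centred) and 3860 in MRL (2091 higher, 1769 lower; 1714 and 2625 centred), the median probe set moving by -0.15 in each with centring. The MRL count was 2413, 2508 and 2433 without day 5 replicates 1, 2 and 4.

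In noninfarct tissue at day 1, neutrophil markers and the acute phase gene Serpina3n rose in both strains. In C57 the largest rises were Lcn2 (7.59 ± 0.40), Serpina3n (6.45 ± 0.41), Timp1 (5.50 ± 0.67), the lipase inhibitor Angptl4 (4.93 ± 0.64) and S100a9 (4.70 ± 0.48). Adjusted p ranged from 1.7e-10 to 0.00016. In MRL they were Timp1 (6.33 ± 0.62), Lcn2 (6.12 ± 0.37), Ankrd2 (4.40 ± 0.61), Serpina3n (4.10 ± 0.38) and Prg4 (4.00 ± 0.44). Their adjusted p lay between 2.5e-09 and 0.00053. Falls were Dbp (-3.19 ± 0.73), the apelin receptor Aplnr (-3.15 ± 0.57), Col15a1 (-3.10 ± 0.59), the transferrin receptor Tfrc (-2.76 ± 0.64) and Asb15 (-2.25 ± 0.58) in C57. These had adjusted p of 0.0033 to 0.034. MRL counterparts were Plekhh1 (-2.32 ± 0.30), Tmod4 (-1.41 ± 0.24), Pfkfb2 (-1.33 ± 0.29), Aspn (-1.26 ± 0.30) and Itih5 (-1.21 ± 0.20). The adjusted p of these genes ran from 0.00027 to 0.047. The chemokine Ccl6 rose in both (3.03 ± 0.34, 3.50 ± 0.31), as did Fhl1 (1.89 ± 0.31, 2.11 ± 0.29). Nppb rose in MRL (2.43 ± 0.40, adjusted p 0.0036) with a value of 1.00 in C57 (adjusted p 0.22). Cdkn1a rose in C57 (3.63 ± 0.55, adjusted p 0.00093) with 1.35 in MRL (0.26). The test of strain by infarction called neither gene. Of 7 neutrophil markers 3 rose in each strain (4 and 3 adjusted over the list alone; adjusted p = 0.04 and 0.016 with an estimated correlation). Of 8 fetal and stress genes 4 and 2 rose (6 and 6; 0.14 and 0.016), and of 15 cytokine genes 3 and 4 (3 and 10; 0.24 and 0.016). In C57 2 of 12 interferon genes fell (7 over the list alone; median -0.85; adjusted p = 0.23 with an estimated correlation).

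Probe sets called in noninfarct tissue at day 1 numbered 492 of 12344 in C57 (335 higher, 157 lower; 935 without the libraries that stood apart) and 121 in MRL (97 higher, 24 lower; 316 without them). The strains shared 64 higher and 6 lower, where chance would give 2.63 and 0.305 (135 and 47 without those libraries, chance 9.89 and 2.93). The C57 count was 177, 256 and 242 without day 0 replicates 1, 2 and 3 and 291 without day 1 replicate 1. In MRL it was 47, 53, 65 and 59 without day 0 replicates 1 to 4, and 212, 45, 55 and 52 without day 1 replicates 1 to 4. The call of Dbp in C57 ended without day 0 replicates 2 or 3 (adjusted p 0.068 to 0.07). That of Tfrc ended without replicates 1, 2 or 3 of that group or day 1 replicate 1 (0.061 to 0.069). That of Asb15 ended without the same 3 replicates or day 1 replicates 1, 3 or 4 (0.051 to 0.12). In MRL the call of Pfkfb2 ended without day 0 replicates 1, 2 or 3 or day 1 replicates 2, 3 or 4 (0.052 to 0.11). That of Aspn ended without any day 0 replicate or day 1 replicates 2, 3 or 4 (0.052 to 0.17).

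In noninfarct tissue at day 5, Sprr1a (6.25 ± 1.05 in C57, 7.34 ± 0.97 in MRL), Timp1 (6.37 ± 0.67, 7.14 ± 0.62), Lgals3 (6.14 ± 0.88, 6.98 ± 0.81), Lox (6.13 ± 0.63, 6.18 ± 0.58) and Tnc (6.03 ± 0.82, 6.61 ± 0.76) had the largest rises in both strains. The adjusted p was at most 0.00089. The falls in C57 were Dbp (-2.58 ± 0.73), Pcp4l1 (-2.31 ± 0.76), Hlf (-2.31 ± 0.42), Kcnip2 (-2.23 ± 0.56) and Yipf7 (-2.22 ± 0.63), with adjusted p 0.0015 to 0.036. For MRL they were Plekhh1 (-2.60 ± 0.30), Ces1d (-2.40 ± 0.59), Asb15 (-2.40 ± 0.54), Wnk2 (-2.31 ± 0.47) and Ift81 (-2.10 ± 0.41). Adjusted p ranged from 7.7e-06 to 0.0061. Of 33 matrix genes 31 rose in C57 and 32 in MRL (32 and 33 adjusted over the list alone; adjusted p = 0.11 for each with an estimated correlation), among them Postn (4.11 ± 0.38, 4.81 ± 0.36), Col1a1 (4.61 ± 0.53, 4.73 ± 0.49) and Fn1 (5.08, 5.33). Macrophage markers rose in 18 and 19 of 23 (19 and 19 over the list alone; adjusted p = 0.14 for each with an estimated correlation). Cell cycle genes rose in 12 and 15 of 20 (13 and 15; 0.19 and 0.2; 8 in C57 without the libraries that stood apart), with Mki67 at 2.95 ± 0.60 and 4.08 ± 0.55. Fibroblast markers rose in 7 and 8 of 9 (7 and 8; 0.11 and 0.068). Nppa rose in both (2.36 ± 0.53, adjusted p 0.006; 2.30 ± 0.49, 0.0023). Fatty acid oxidation genes fell in 10 of 20 in C57 and 5 in MRL (15 and 10 over the list alone; 2 and 17 without the libraries that stood apart; adjusted p = 0.32 and 0.46 with an estimated correlation). Oxidative phosphorylation genes fell in 9 and 2 of 22 (20 and 0 over the list alone; 3 and 18 without those libraries; 0.32 and 0.46). Myh6 (-0.40, -0.23), S100a8 (0.15, 0.05) and Il6 (0.36, 0.11) were not called.

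Probe sets called in noninfarct tissue at day 5 numbered 2602 in C57 (1435 higher, 1167 lower; 1409 and 1438 after quantile normalization, 1329 and 1511 centred) and 2990 in MRL (1981 higher, 1009 lower; 1740 and 1852 after quantile normalization, 1647 and 2014 centred, the median probe set moving by -0.13 with centring). Without the libraries that stood apart they numbered 1246 (850 higher, 396 lower) and 4294. The C57 count was 1675, 1199 and 1154 without day 0 replicates 1, 2 and 3. It was 4612 without day 5 replicate 1 and 1246 without day 5 replicate 3. The MRL count was 1739 without day 5 replicate 2. Chance was not excluded for the C57 count, since rearranged labels called up to 4960. The calls of Dbp in C57 ended without day 0 replicates 2 or 3 (adjusted p 0.068 to 0.07). Those of Pcp4l1 and Yipf7 ended without day 0 replicates 1, 2 or 3 (0.071 to 0.11 and 0.055 to 0.059). Without day 5 replicate 3 the log2 changes were -1.13 for Pcp4l1 and -1.29 for Yipf7. The strains shared 1241 higher and 497 lower probe sets, where chance would give 230 and 95.4. Without the libraries that stood apart these were 814 and 317 (chance 166 and 60.4).

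Between the strains, signals of MHC genes and of genes of unrelated roles differed before infarction. Variants under the probes were not excluded. In day 0 infarct-region tissue MRL was higher than C57 for Abhd1 (log2 difference 4.00 ± 0.40), the glycosyltransferase B4galnt2 (3.97 ± 0.76), Plekhh1 (3.44 ± 0.40), the transcription factor Nfia (3.07 ± 0.54) and Sorl1 (2.87 ± 0.46). It was lower for Pttg1 (-4.10 ± 0.39), the MHC class I gene H2-D1 (-4.08 ± 0.56), the cytokine Il15 (-3.79 ± 0.51), the MHC class II gene H2-Aa (-3.66 ± 0.64) and Cyfip2 (-3.50 ± 0.74). Their adjusted p lay between 2.5e-06 and 0.015. In the noninfarct region at day 0 Abhd1 (4.10 ± 0.43), B4galnt2 (4.05 ± 0.64), Thrsp (3.24 ± 0.56), Plekhh1 (3.11 ± 0.32) and Sorl1 (2.94 ± 0.49) were higher. There Pttg1 (-4.44 ± 0.37), Rpgrip1 (-4.23 ± 0.63), H2-Aa (-4.09 ± 0.69), H2-D1 (-3.95 ± 0.66) and Cyfip2 (-3.75 ± 0.58) were lower. These had adjusted p of 1.5e-06 to 0.0018. The skeletal actin gene Acta1, of the fetal and stress list, was higher in MRL at day 0 in infarct-region (2.28 ± 0.33, adjusted p 0.00034) and noninfarct tissue (1.75 ± 0.36, 0.0099). Of 10 MHC and antigen presentation genes 4 were lower in infarct-region tissue (7 over the list alone; median -1.61). In noninfarct tissue 6 of 9 were lower (7 lower and 1 higher over the list alone; median -2.08), with adjusted p = 0.00056 and 0.0098 with an estimated correlation. Interferon genes were lower in 1 of 13 (4 over the list alone; adjusted p = 0.19 with an estimated correlation) and in 5 of 12 (7 over the list alone; 0.011), among them Ifit3 in noninfarct tissue (-2.27 ± 0.38). Calls numbered 137 in infarct-region tissue (86 higher, 51 lower) and 222 in noninfarct tissue (118 higher, 104 lower; 105 and 122 centred; 369 without the libraries that stood apart), where rearranged labels called at most 4 and 5. The count was 75 and 76 without C57 infarct replicates 1 and 2, and 137 without C57 noninfarct replicate 3. The call of Cyfip2 in infarct-region tissue ended without any C57 replicate or MRL replicate 2 (adjusted p 0.054 to 0.083). That of Acta1 in noninfarct tissue ended without C57 replicate 1 (0.081).

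At day 1 the largest strain differences in infarct tissue were B4galnt2 (3.20 ± 0.71), Cuedc1 (3.07 ± 0.30), Abhd1 (2.92 ± 0.37), Wdfy1 (2.89 ± 0.51) and Acta1 (2.85 ± 0.30), higher in MRL. Lower in MRL were Rpgrip1 (-4.78 ± 0.66), H2-D1 (-4.56 ± 0.52), Pttg1 (-3.87 ± 0.36), H2-K1 (-3.25 ± 0.56) and Cyfip2 (-2.98 ± 0.68). The adjusted p of these genes ran from 2.9e-06 to 0.038. Noninfarct tissue gave B4galnt2 (3.99 ± 0.60), Abhd1 (3.31 ± 0.40), Serpina1b (2.98 ± 0.41), Pam (2.78 ± 0.44) and Wdfy1 (2.72 ± 0.44), and Rpgrip1 (-4.42 ± 0.59), Pttg1 (-4.34 ± 0.35), H2-D1 (-4.06 ± 0.61), Cyfip2 (-4.03 ± 0.54) and Stk25 (-3.50 ± 0.47). All had adjusted p of at most 0.00067. One other probe set of H2-D1 was called in the opposite direction in both tissues. The platelet chemokine Ppbp was lower in MRL noninfarct tissue (-3.19 ± 0.39, adjusted p 4.9e-05). The smooth muscle actin gene Acta2 was the only index gene called in any of the strain comparisons, lower in MRL noninfarct tissue (-0.96 ± 0.20, adjusted p 0.01). Among neutrophil markers 2 of 7 were lower in MRL infarct tissue (2 adjusted over the list alone; median -0.81; adjusted p = 0.074 with an estimated correlation), including the interleukin receptor Il1r2 (-2.03 ± 0.37). Of 10 MHC genes 2 were lower and 1 higher in infarct tissue (2 and 1 over the list alone; adjusted p = 0.38 with an estimated correlation). Calls numbered 128 in infarct tissue (47 higher, 81 lower) and 342 in noninfarct tissue (177 higher, 165 lower; 169 and 200 centred; 632 without the libraries that stood apart), and chance was not excluded for either. Rearranged labels called up to 379 in noninfarct tissue and up to 594 in infarct tissue. The count in infarct tissue was 79, 81 and 225 without MRL replicates 1, 2 and 3. In noninfarct tissue it was 207 and 527 without C57 replicates 1 and 2 and 209 without MRL replicate 1. In infarct tissue the call of B4galnt2 ended without C57 replicates 1, 2 or 4 or MRL replicates 1, 3 or 4 (adjusted p 0.05 to 0.089). That of Cyfip2 ended without C57 replicates 1 or 2 or MRL replicates 1, 2 or 4 (0.055 to 0.13).

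At day 5, of groups without overlap, the strain differences in infarct tissue were led by Rbp7 (2.43 ± 0.51), Alad (2.06 ± 0.28), Cuedc1 (1.80 ± 0.30), Abhd1 (1.67 ± 0.37) and Glo1 (1.20 ± 0.21), higher in MRL. Lower in MRL were H2-D1 (-4.20 ± 0.52), H2-K1 (-3.57 ± 0.56), Fcgr4 (-3.48 ± 0.27), Galc (-2.77 ± 0.30) and Ms4a4c (-2.68 ± 0.30). Adjusted p ranged from 2.3e-07 to 0.035. In noninfarct tissue B4galnt2 (3.98 ± 0.60), Serpina1b (3.15 ± 0.41), Abhd1 (2.99 ± 0.40), Pam (2.81 ± 0.44) and Thrsp (2.69 ± 0.52) were higher and H2-D1 (-3.73 ± 0.61), Rpgrip1 (-3.33 ± 0.59), H2-K1 (-2.92 ± 0.53), Pttg1 (-2.20 ± 0.35) and Il15 (-2.15 ± 0.44) lower. Their adjusted p lay between 0.00016 and 0.011. One other probe set of H2-D1 was called in the opposite direction in infarct tissue. Interferon genes were lower in MRL in 6 of 13 in infarct tissue (13 adjusted over the list alone; median -1.59; 8 without the libraries that stood apart). They were lower in 3 of 12 in noninfarct tissue (8 over the list alone; median -0.82; 6 without them), with adjusted p = 0.0023 and 0.015 with an estimated correlation. MHC genes were lower in 2 of 10 (5 over the list alone; adjusted p = 0.0023 with an estimated correlation) and 4 of 9 (4; 0.015). Calls numbered 88 in infarct tissue (23 higher, 65 lower; 310, 165 higher and 145 lower, without the libraries that stood apart) and 154 in noninfarct tissue (106 higher, 48 lower; 87 and 78 centred; 479 without those libraries), and chance was not excluded for either. Rearranged labels called up to 220 in noninfarct and 693 in infarct tissue, some moving a library that stood apart to the other strain. The infarct count was 140, 55 and 50 without C57 replicates 1, 3 and 4. It was 52, 54 and 310 without MRL replicates 1, 2 and 3. In noninfarct tissue it was 479 and 101 without C57 replicates 3 and 4. The calls of Rbp7 in infarct tissue ended without C57 replicates 2 or 4 or MRL replicates 2 or 4 (adjusted p 0.071 to 0.11). Those of Abhd1 ended without C57 replicates 2, 3 or 4 or MRL replicates 1, 2 or 4 (0.093 to 0.18). In noninfarct tissue the call of Il15 ended without C57 replicate 2 (0.058).

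Over the 3 days, 21 probe sets were called in the same direction in infarct tissue (9 higher in MRL, 12 lower; 61 without the libraries that stood apart) and 89 in noninfarct tissue (63 higher, 26 lower; 181 without them). Independent lists would share 0.000564 and 0.00163, and 0.0145 and 0.00541. The infarct count was 11 without C57 day 0 replicate 2, 12 without MRL day 0 replicate 1 and 61 without MRL day 5 replicate 3. The noninfarct count was 181 without C57 day 5 replicate 3. Of 7258 genes, 7 were higher and 5 lower in MRL in all 6 comparisons (13 and 15 without those libraries). Mean log2 differences were 3.17 for Abhd1, 2.42 for Pam, 2.37 for Alad, 2.25 for Cuedc1, 1.34 for Glo1 and 1.30 for Tmem144. They were -1.95 for the interferon-induced Rsad2, -3.00 for H2-K1, -3.02 for Stk25, -4.02 for Rpgrip1 and -4.10 for H2-D1. In MRL at day 0 Stk25 (2.68) and Rpgrip1 (3.06) lay below the median of every array, as Abhd1 did in C57 (3.88), so these sizes are not exact. Other probe sets, in infarct and noninfarct tissue at days 0 and 1, averaged 0.60 and 0.38 for Cuedc1 and -0.61 and -0.44 for H2-D1. They averaged 1.62 and 1.56 for Glo1, 2.89 and 2.13 for Tmem144 and -1.67 and -1.23 for Rsad2. Those of H2-K1 averaged -2.76 and -2.90, with 1 of 3 at -6.87 and -7.35.

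**Figure D4:**
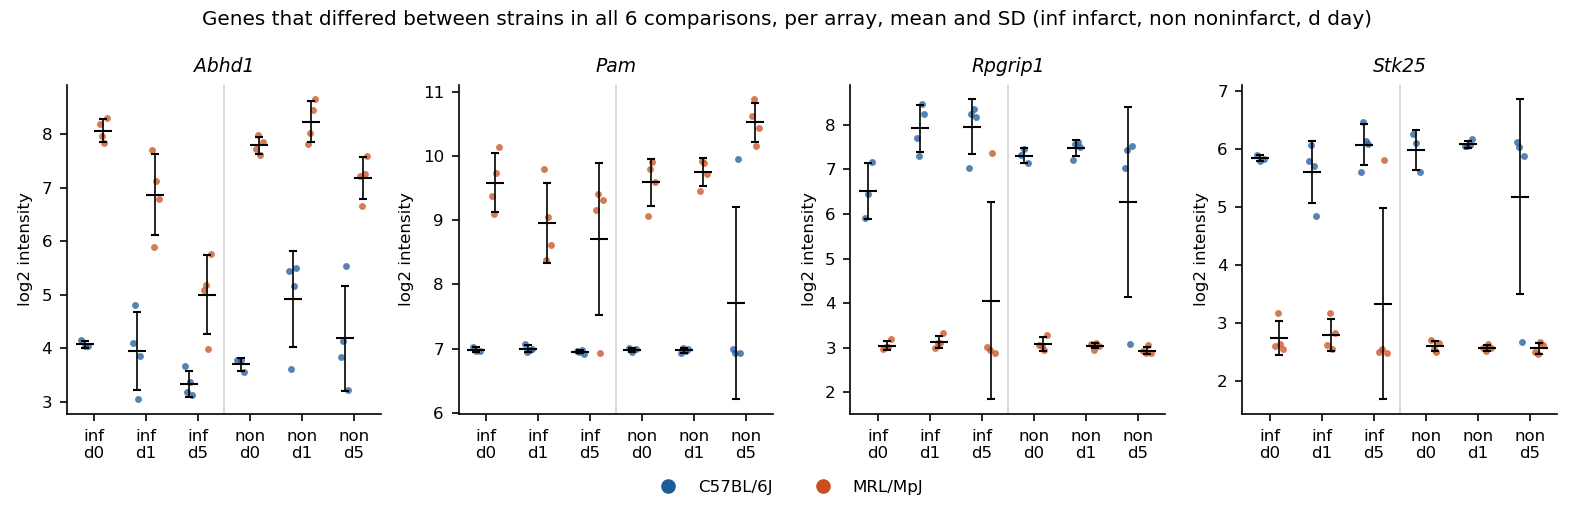
Log2 intensity (vertical axis) per array (points, colored by strain) of genes that differed between the strains in all 6 comparisons, by day and region, with the mean (dash) and SD (bar) of each group of 4 arrays, or 3 in the C57 day 0 groups. At day 0 Abhd1 averages 3.88 in C57 and 7.93 in MRL, and Rpgrip1 6.91 and 3.06.

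The response to infarction in infarct tissue at day 1 was lower in MRL for 6 probe sets, among them the vessel-stabilizing factor Angpt1 (difference of log2 changes -1.92 ± 0.28, adjusted p 0.0044) and the potassium channel Kcnj5 (-1.36 ± 0.20, adjusted p 0.0044). At day 5 20 probe sets differed, 3 higher and 17 lower: the change was higher in MRL for Il15 (3.95 ± 0.70), Pttg1 (3.20 ± 0.53) and Phkg1 (1.84 ± 0.35). It was lower for Plekhh1 (-3.49 ± 0.54), Fcgr4 (-3.46 ± 0.39), Ms4a4c (-2.62 ± 0.44), Kcnj15 (-1.93 ± 0.33) and Angpt1 (-1.85 ± 0.28). These had adjusted p of 8.3e-05 to 0.025. In noninfarct tissue 1 probe set was called on each day, the interferon-inducible GTPase Gbp3 at day 1 (2.31 ± 0.31, adjusted p 0.0044) and the macrophage receptor Vsig4 at day 5 (2.28 ± 0.30, adjusted p 0.0031). Unadjusted p under 0.05 gave 478, 443, 413 and 227 probe sets in these 4 limma comparisons. No index gene was called, the difference being -1.64 ± 0.59 for Cdkn1a and 1.19 ± 0.52 for Nppb in infarct tissue at day 1. The list tests called with the preset correlation were not called with an estimated one, such as interferon genes in noninfarct tissue at day 1 (median 0.86; 6 of 12 over the list alone; adjusted p = 0.077 with an estimated correlation) and MHC genes there (median 0.83; 3 of 9 over the list alone; 0.077).

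The 4 counts were 1, 4, 0 and 0 with the stricter filter, 37, 169, 10 and 8 with array weights, and 3 and 11 in infarct tissue with arrays centred. In simulated data of infarct tissue at day 5 such a test called 12 of 100 differences of log2 1. Without the libraries that stood apart, 8, 74 (40 higher, 34 lower), 1 and 10 probe sets were called for strain by infarction, with 3.28 for Il15 and 2.78 for Pttg1. The infarct day 1 count was 16 without MRL day 1 infarct replicate 3, and the day 5 count 12 without C57 day 0 infarct replicate 3, 36 without C57 day 5 infarct replicate 1 and 74 without MRL day 5 infarct replicate 3. In noninfarct tissue the day 1 count was 2, 3 and 2 without C57 day 1 replicates 1, 2 and 3 and 6 without MRL day 1 replicate 3. The day 5 count there was 4 and 10 without C57 day 5 replicates 1 and 3. With an offset of 32 the calls of Angpt1 on both days, Kcnj5, Kcnj15, Ms4a4c, Phkg1, Gbp3 and Vsig4 ended (adjusted p 0.066 to 0.24). With arrays centred those of Kcnj5 (0.089) and Phkg1 (0.051) ended, and with all 46 arrays in one fit that of Vsig4 (0.23). The calls of Il15 and Kcnj15 ended without C57 day 0 infarct replicate 3 (adjusted p 0.069 and 0.051). The call of Phkg1 ended without C57 day 0 infarct replicates 2 or 3, C57 day 5 infarct replicates 2, 3 or 4, any MRL day 0 infarct replicate, or MRL day 5 infarct replicates 2 or 4 (0.05 to 0.1). Chance was not excluded for any of the 4 counts. Rearranged labels called up to 16, 61, 243 and 220. They also mix the strains at day 0, which can carry strain differences into the test, and so do not decide.

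Before infarction the regions differed in atrial genes. In MRL at day 0 the atrial light chain genes Myl7 (-5.70 ± 0.98, adjusted p 0.0073) and Myl4 (-4.33 ± 0.85, 0.044) and the calcium pump inhibitor Sln (-4.46 ± 0.90, 0.048) were lower in the infarct region, and Slc22a23 (1.18 ± 0.19, 0.006) was higher. These were all 4 calls of 13138 probe sets (81 with unadjusted p under 0.05). In C57 none was called in limma (198 unadjusted; 10 of 10 rearrangements called as many or more, up to 3, too few for a share under 0.05). Of 5 atrial and conduction markers 3 were lower in MRL (4 over the list alone; median -4.33; adjusted p = 1.1e-09 with an estimated correlation) and none in C57 (4 over the list alone; median -2.93; 0.00053). The MRL count was 2 and 2 without infarct replicates 2 and 3, and 2, 1 and 2 without noninfarct replicates 1, 3 and 4. The call of Myl7 ended without MRL day 0 noninfarct replicate 3 (0.072), and those of Sln (0.088 to 0.45) and Myl4 (0.084 to 0.38) without any of the 8 arrays.

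At day 1 cytokine, neutrophil and chaperone genes were higher in infarct than in noninfarct tissue. In C57 the largest differences were Cxcl2 (5.78 ± 0.81), Hspa1a (5.37 ± 0.95), Il6 (4.46 ± 0.87), Hspa1b (4.40 ± 0.65) and the adhesion molecule Selp (4.29 ± 0.51). In the other direction stood Myl7 (-4.23 ± 0.98), Myl4 (-3.42 ± 0.85), Retsat (-2.28 ± 0.44), Smim27 (-2.28 ± 0.36) and Irs1 (-2.19 ± 0.48). The adjusted p of these genes ran from 1.5e-06 to 0.012. The MRL genes were S100a8 (3.94 ± 0.55), Slfn4 (3.90 ± 0.54), Adam8 (3.73 ± 0.82), Cd14 (3.65 ± 0.58) and Clec4d (3.34 ± 0.75), and lower Myl7 (-4.71 ± 0.98), Myl4 (-3.79 ± 0.85), Sln (-3.19 ± 0.90), Olfml2b (-2.45 ± 0.46) and Slc25a42 (-2 ± 0.61). Adjusted p ranged from 4.5e-05 to 0.034. Cytokine genes were higher in 14 of 19 in C57 and 11 in MRL (14 and 15 adjusted over the list alone; adjusted p = 0.0057 and 0.035 with an estimated correlation). Heat shock genes were higher in 10 and 9 of 14 (10 each, with 1 lower in C57; 0.0017 and 0.023) and neutrophil markers in 4 of 7 in each (6 and 5; 0.00068 and 0.004). Calls numbered 960 in C57 (516 higher, 444 lower; 1829 without the libraries that stood apart) and 1219 in MRL (583 higher, 636 lower; 775 and 419 with arrays centred; 2167 without those libraries; 2082 with the replicate number as a block). Chance was not excluded for C57, where rearranged labels called up to 1597. The C57 count was 1930, 282 and 417 without infarct replicates 2, 3 and 4, and 376 and 399 without noninfarct replicates 1 and 3. The MRL count was 1969, 384 and 568 without infarct replicates 1, 2 and 4, and 355, 767 and 565 without noninfarct replicates 1, 3 and 4. The call of Myl4 in C57 ended without noninfarct replicate 1 (adjusted p 0.053). In MRL that of Sln ended without infarct replicates 2 or 4 or noninfarct replicates 1 or 2 (0.055 to 0.1). That of Slc25a42 ended without infarct replicates 2 or 4 or noninfarct replicates 1 or 4 (0.057 to 0.19).

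At day 5 infarct tissue held more Ly86, an immune cell gene, and less Smyd1, a muscle methyltransferase gene, than noninfarct tissue in both strains. In C57 Ly86 (3.36 ± 0.55), Clec4d (3.24 ± 0.75), Fcgr4 (3.16 ± 0.31), Plac8 (2.95 ± 0.67) and Slfn4 (2.71 ± 0.54) were higher and Smyd1 (-2.85 ± 0.46), Rbp7 (-1.93 ± 0.46), Mccc2 (-1.49 ± 0.35), Homer1 (-1.39 ± 0.41) and Plpp7 (-1.38 ± 0.33) lower, with adjusted p of 8.3e-09 to 0.034. In MRL Ly86 (2.43 ± 0.55), Capg (2.31 ± 0.56), Dok1 (1.92 ± 0.44), Cdca3 (1.77 ± 0.42) and Myo7a (1.75 ± 0.40) were higher and Kcnip2 (-3.09 ± 0.76), Thrsp (-3.03 ± 0.65), Ift81 (-2.83 ± 0.55), Serpina1b (-2.73 ± 0.41) and Smyd1 (-2.61 ± 0.46) lower. Their adjusted p lay between 0.00017 and 0.0096. Fatty acid oxidation genes were lower in 11 of 20 in C57 and 17 in MRL (14 and 19 adjusted over the list alone; 18 and 19 without the libraries that stood apart; adjusted p = 0.28 and 0.27 with an estimated correlation). Sarcomere genes were lower in 3 of 22 in C57 and 16 in MRL (10 and 20 over the list alone; 17 and 20 without those libraries; adjusted p = 0.28 and 0.27 with an estimated correlation). Macrophage markers were higher in 11 and 4 of 23 (19 and 9 over the list alone; 20 and 18 without them; 0.28 and 0.44).

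Probe sets called between the regions at day 5 numbered 1121 in C57 (664 higher, 457 lower; 512 and 674 centred; 2310 and 1952 without the libraries that stood apart) and 1842 in MRL (589 higher, 1253 lower; 794 and 1036 centred; 2219 and 2417 without them). Rearranged labels called up to 5072 and 3654, but some move a library that stood apart to the other region, so they do not decide. A fit of only the groups compared called 0 in C57 and 12 in MRL, and the replicate block 2563 and 2790. The C57 count was 3206, 108, 282 and 165 without infarct replicates 1 to 4, and 99, 337, 3828 and 471 without noninfarct replicates 1 to 4. The MRL count was 427, 213, 4318 and 480 without infarct replicates 1 to 4, and 1027, 914 and 871 without noninfarct replicates 1, 3 and 4. In C57 the calls of Plac8, Mccc2, Homer1 and Plpp7 ended without infarct replicates 2 or 4 or noninfarct replicate 1. That of Rbp7 ended without infarct replicates 2 or 4, and that of Clec4d without infarct replicate 2 or noninfarct replicate 1. That of Homer1 also ended without noninfarct replicates 2 or 4 (adjusted p 0.05 to 0.18 for all). In a fit of only the groups compared all 10 named C57 calls ended (adjusted p 0.32 to 0.33), and in MRL those but Serpina1b (0.062 to 0.16). In MRL the calls of Capg (0.053), Cdca3 (0.064) and Kcnip2 (0.06) ended without infarct replicate 2.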

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

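The tests of the pair of libraries that stood apart and of the share of muscle cells were chosen after the results were seen, those of strain variants under the probes and of rearranged labels before.

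Among 150 pairs of an index gene and a group of 4 arrays, 11 held an array far from the other 3, measured as its gap to the nearest array over the range of the group, and chance flags about 1 in 20 groups. In MRL day 1 infarct tissue Nppa was low in replicate 3 (0.889; 12.37 against 14.38 for the nearest), and Myh7 (0.887; 11.43 against 9.55) and Mki67 (0.962; 5.61 against 3.56) were high in replicate 1. In MRL day 5 infarct tissue replicate 3 was high for Nppb (0.949; 12.83 against 11.16) and low for Col3a1 (0.933; 13 against 14.11). Replicate 3 of C57 day 5 noninfarct tissue was low for Myh6 (0.833; 14.28 against 15.18) and replicate 1 of that group for Mki67 (0.834; 3.61 against 7.17). Il6 was high in noninfarct tissue at day 1 in MRL replicate 3 (0.94; 6.95 against 3.37) and C57 replicate 4 (0.898; 5.21 against 3.36). Timp1 was low in MRL day 0 infarct replicate 2 (0.833; 1.96 against 2.16), and Cdkn1a was high in C57 day 5 infarct replicate 4 (0.875; 9.33 against 8.56).

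The change after infarction differed between the strains, by a test of the difference itself, for 6 probe sets in infarct tissue at day 1, among them Angpt1 (-1.92) and Kcnj5 (-1.36). At day 5 it differed for 20, among them Il15 (3.95), Pttg1 (3.20), Phkg1 (1.84), Plekhh1 (-3.49), Fcgr4 (-3.46), Ms4a4c (-2.62), Kcnj15 (-1.93) and Angpt1 (-1.85). In noninfarct tissue it differed for 1 at day 1, Gbp3 (2.31), and for 1 at day 5, Vsig4 (2.28).

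For the libraries that stood apart, exchanged labels were weighed against an unusual tissue sample or infarct size with the strain label right. A score from 68 probe sets that differ between the strains at days 0 and 1, 28 of them higher in MRL, was 0.82 in the library labelled C57 and -0.05 in the one labelled MRL. Other day 5 arrays, which had no part in the choice of the probe sets, lay at -0.18 to 0 in C57 and 0.9 to 1.04 in MRL, so the scores are consistent with exchanged labels. Myl7, low in infarct tissue, was 8.32 in the library labelled infarct (at most 4.43 in all other infarct arrays) and 2.73 in the one labelled noninfarct, but also 2.53 in MRL day 5 noninfarct replicate 4. The score of 0.82 argues against an unusual sample of a C57 heart, and no other explanation was tested.

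For probe sets that differ between the strains on all 3 days, a strain variant under the probes was weighed against a difference of the gene, by the strain difference of other probe sets of the same gene relative to the called one. The median ratio was 0.2 for genes lower in MRL (13 genes, 95% interval 0.08 to 0.59, 2 opposite in sign) and 0.75 for genes higher in MRL (24 genes, 0.23 to 1, 4 opposite). Both leave open whether such variants account for these differences, MHC genes included.

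Lower muscle and energy genes in day 5 infarct tissue were weighed against a lower share of cardiac muscle cells as the whole cause. Macrophage minus endothelial medians were 2.6 to 4.4 in the 7 arrays (1.7 in the library that stood apart), against -0.12 to 0.11 at day 0. They do not tell, as other cells need not change alike. Fatty acid oxidation minus sarcomere medians, at most -0.49, do not tell, since sarcomere genes lie nearer the array maxima (medians 13.44 and 12.52 at day 0, maxima from 14.82), where changes can be compressed. A lower share alone would lower muscle genes of like level alike if other cells held little of these transcripts, which was not tested. Among members over 1 log2 unit below these maxima (medians 12.62 and 12.35) the difference was -1.23 to -0.48 (-0.69 in that library). At day 0 it was -0.07 to 0.07. Only if other cells held little of these transcripts do the values of these members argue against a lower share as the whole cause. A part of it is not excluded.

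Within a region, chance was excluded where 1 of 35 ways of splitting the arrays, the real one, called as many probe sets. With the highest other value in brackets, these were C57 infarct day 1 with 1995 (1517), MRL infarct day 1 with 2760 (2) and day 5 with 6022 (3599), C57 noninfarct day 1 with 492 (375), and MRL noninfarct day 1 with 121 (3) and day 5 with 2990 (1). Day 5 against day 1 gave 4394 (3261) in C57 and 3860 (3437) in MRL, and the strains at day 0 gave 137 (4) in infarct and 222 (5) in noninfarct tissue. The MRL regions at day 0 also gave 4 (2) with 1 of 35. Both regions come from the same hearts, so splits across them do not decide, and chance was not excluded there. Chance was excluded for strain differences shared by all days, 21 (0) and 89 (0), with 1 of 100. For strain by infarction in infarct tissue 4 of 100 ways called as many at day 1, 6 (16), and at day 5, 20 (61). These ways also mix strains at day 0 and do not decide.

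Chance was not excluded for C57 infarct day 5 with 2 of 35 splits, 5480 (5632), and C57 noninfarct day 5 with 2, 2602 (4960), nor for the strains in infarct tissue at day 1 with 4, 128 (594), and day 5 with 4, 88 (693), nor in noninfarct tissue at day 1 with 2, 342 (379), and day 5 with 2, 154 (220). The same holds for the C57 regions at day 1 with 3, 960 (1597), and day 5 with 2, 1121 (5072), and for the MRL regions at day 5 with 5, 1842 (3654). It holds for strain by infarction in noninfarct tissue with 13 of 100 at day 1, 1 (243), and 15 at day 5, 1 (220), and for the list tests with 4 of 40, 247 (251). A split with several times the real count points to a structure of the samples. For day 5 against day 0, C57 splits that keep 3 day 5 arrays together are near the real one and do not test chance. For the C57 regions at day 0 all 10 splits called as many, 0 (3), and 10 splits are too few for a share under 0.05. For the MRL regions at day 1 the real split alone, 1 of 35, called as many, 1219 (592), but the numbers pair these arrays, and the 8 splits that part all 4 pairs (highest other 1) are too few for a share under 0.05. The 592 came from the 27 that do not.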

How the results depend on the processing

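The fits without the pair of libraries that stood apart, the replicate block for the shared strain differences, and the arrays left out for those and for the list tests were chosen after seeing the data, the other settings before. Quantile normalization and an intensity trend with a robust prior moved none of 26 counts by over 1.5 times, and fry and the mean of all probe sets gave 185 and 244 list tests against 247. Of 3482 checks of named genes under other settings 3409 kept their call, 73 lost it and 0 reversed, and with 1 array left out 2631 of 2777 kept it, 146 lost it and 0 reversed. Signal over background limits dim probe sets. Where no cause is given below, the cause was not tested.

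With no filter, which tests more probe sets, 8146 were called for C57 infarct day 5 against day 1, 598 for the C57 regions at day 5, 12 for strain by infarction in infarct tissue at day 1, and 2 and 2 in noninfarct tissue at days 1 and 5. The stricter filter, which tests fewer, gave 90 and 35 for the strains in infarct tissue at days 0 and 5 and 99 in noninfarct tissue at day 5, 1, 4, 0 and 0 for strain by infarction (infarct days 1 and 5, noninfarct days 1 and 5), and 2 for the MRL regions at day 0. Centred arrays gave 3 and 11 for strain by infarction in infarct tissue, and the offset gave 2 for the MRL regions at day 0. An adjusted p under 0.01 left 9 and 50 shared strain differences in infarct and noninfarct tissue, and the estimated correlation left 37 list tests.

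Array weights moved 20 of 26 counts. Changes after infarction gave 4038 in C57 and 5336 in MRL infarct tissue at day 1, 770 and 934 in noninfarct tissue at day 1 and 6255 in MRL at day 5. The strains gave 715 and 480 in infarct tissue at days 0 and 5, and 651, 639 and 474 in noninfarct tissue at days 0, 1 and 5. Strain by infarction gave 37 and 169 in infarct and 10 and 8 in noninfarct tissue. The regions at days 0, 1 and 5 gave 2, 1976 and 4663 in C57 and 9, 3227 and 5705 in MRL.

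All 46 arrays in one fit gave 3154 for C57 infarct day 1, 1424 for C57 noninfarct day 5, 215, 275 and 169 for the strains in infarct tissue at days 0, 1 and 5, 13 and 36 for strain by infarction in infarct tissue and 2 and 0 in noninfarct tissue, and 32 shared strain differences in infarct tissue. Only the groups compared, with fewer arrays for the spread, gave 1, 99 and 0 for the C57 regions at days 0, 1 and 5, and 363 and 12 for the MRL regions at days 1 and 5.

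Without the libraries that stood apart, the strains gave 310 in infarct tissue at day 5 and 369, 632 and 479 in noninfarct tissue at days 0, 1 and 5, with 61 and 181 shared by all days. Strain by infarction gave 74 in infarct and 10 in noninfarct tissue at day 5. Noninfarct tissue gave 935 and 1246 for C57 at days 1 and 5 and 316 for MRL at day 1. The regions gave 2, 1829 and 4262 in C57 at days 0, 1 and 5, and 2167 and 4636 in MRL at days 1 and 5.

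With the replicate number as a block, 199 probe sets were called for MRL noninfarct day 1, 1669 and 2563 for the C57 regions at days 1 and 5, and 2082 and 2790 for the MRL regions at days 1 and 5. The block ended the calls of Nppa in C57 infarct tissue at day 1 (adjusted p 0.08) and of B4galnt2 between the strains in infarct tissue at day 1 (0.054), and changed no other call of a named gene and no other count by over 1.5 times. Same-numbered arrays of the regions correlated by -0.46 to 0.15 in C57 day 1, -0.01 to 0.77 in C57 day 5, 0.07 to 0.55 in MRL day 0 and -0.02 to 0.47 in MRL day 5, with 0, 2, 2 and 2 of 4 pairs best with their own number. In C57 day 0 and MRL day 1 all 3 and all 4 were.

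Beside those given with the results, no filter ended the calls of Efnb3 in MRL infarct tissue at day 1, Asb15 in C57 and Aspn and Pfkfb2 in MRL noninfarct tissue at day 1, Pcp4l1 in C57 noninfarct tissue at day 5, B4galnt2 and Cyfip2 between the strains in infarct tissue at day 1, Abhd1 and Rbp7 at day 5, and Homer1 (C57 day 5), Myl4 and Sln (MRL day 0) and Slc25a42 (MRL day 1) between the regions. The offset ended Aspn, B4galnt2, Cyfip2, Abhd1, Rbp7, Homer1, Myl4 and Sln in the same comparisons, Slfn4 between the C57 regions at day 5 and Il15 between the strains in noninfarct tissue at day 5. All 46 arrays in one fit ended Kcnip2, Pcp4l1 and Yipf7 in C57 noninfarct tissue at day 5 and Aspn and Tmod4 in MRL at day 1, and array weights ended Dbp in C57 at day 5. Only the groups compared ended Irs1 (C57 day 1), Slc22a23 (MRL day 0), and Olfml2b, Slc25a42 and Sln (MRL day 1) between the regions.

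With 1 array left out in turn, counts of changes after infarction ran from 1181 to 2347 and 4267 to 6064 in C57 infarct tissue at days 1 and 5, 1612 to 3061 and 5047 to 6754 in MRL, 177 to 634 and 1154 to 4612 in C57 noninfarct tissue, and 45 to 212 and 1739 to 2474 in MRL. Day 5 against day 1 ran from 3001 to 5057 in C57 and 2413 to 5316 in MRL. The strains ran from 75 to 120, 79 to 225 and 50 to 310 in infarct tissue at days 0, 1 and 5, and 137 to 175, 207 to 527 and 101 to 479 in noninfarct tissue. Strain by infarction ran from 6 to 16 and 12 to 74 in infarct and 1 to 6 and 1 to 10 in noninfarct tissue, and shared strain differences from 11 to 61 and 66 to 181. The regions ran from 0 to 0, 282 to 1930 and 99 to 3828 in C57, and 1 to 4, 355 to 1969 and 213 to 4318 in MRL. List tests past the threshold ran from 232 to 259.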

Other observations

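Of 13 genes of the daily cycle, looked up after Dbp was seen and not tested as a list, 2 rose and 4 fell in C57 infarct tissue at day 1 and 1 rose and 5 fell at day 5, and in MRL 1 rose and 3 fell, and 1 rose and 7 fell. In noninfarct tissue 2 fell at day 1 and 5 at day 5 in C57, and in MRL 0 were called at day 1 and 1 rose and 2 fell at day 5. In C57 infarct tissue Dbp fell at day 1 (-3.71 ± 0.71) and day 5 (-3.58 ± 0.71), Hlf fell (-2.23 ± 0.45, -2.89 ± 0.45), as did Tef (-1.63 ± 0.38, -1.73 ± 0.38) and Nr1d2 (-1.79 ± 0.35, -1.63 ± 0.35). At day 1 Nfil3 (1.90 ± 0.54) and Bhlhe40 (1.39 ± 0.33) rose. Arntl rose at day 5 (1.94 ± 0.52, adjusted p = 0.0052) and was not called at day 1 (1.46 ± 0.52, 0.059). In MRL infarct tissue Hlf (-1.43 ± 0.42, -2.80 ± 0.42) and Nr1d2 (-1.04 ± 0.32, -1.37 ± 0.32) fell on both days, and Dbp fell at day 5 (-1.65 ± 0.66, 0.045) but was not called at day 1 (-1.02 ± 0.66, 0.28). In noninfarct tissue at day 1 Dbp fell in C57 (-3.19 ± 0.73, 0.017) and was not called in MRL (-0.54 ± 0.68, 0.84). Nr1d1, Per1 and Clock were called in no change after infarction. The test of strain by infarction called none of the 13, Dbp in infarct tissue at day 1 included (2.69 ± 0.97, adjusted p = 1). The labels give no hour of tissue collection.

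Of 13 cell cycle inhibitors and p53 targets 3 rose in C57 infarct tissue at day 1 and 3 rose and 1 fell in MRL (adjusted p = 0.71 and 0.69 with an estimated correlation). Of 4 erythroid and platelet markers 2 rose in each strain at day 1 (0.14 and 0.15), and of 3 atrial and conduction markers 2 rose in each at day 5 (0.18 and 0.16). Growth factor genes rose in 9 of 19 and fell in 3 in each strain at day 5 (0.18 and 0.22). Glycolysis and hypoxia genes rose in 3 and 4 of 16 and fell in 6 in each at day 5, with medians of -0.09 and -0.07 and means of 0.1 and 0.09. In noninfarct tissue at day 5 complement genes rose in 5 of 7 in C57 and 4 in MRL (0.19 and 0.27). Among lists with 1 or 2 genes tested, Thy1, a gene of T lymphocytes and of fibroblasts, rose in infarct tissue at day 5 (4.04 ± 0.39 in C57, 3.29 ± 0.36 in MRL), while Cd4 fell in MRL (-0.41 ± 0.16, adjusted p = 0.042) and was not called in C57 (-0.31 ± 0.17, 0.15). The B lymphocyte marker Ms4a1 fell from day 1 to day 5 in MRL infarct tissue (-0.62, 0.043), and the mast cell gene Tpsb2 fell in MRL noninfarct tissue at day 5 (-0.37, 0.036). The adipose marker Cidea fell in MRL infarct tissue at day 5 (-1.33), the nerve and Schwann cell marker was called in no comparison, and skeletal muscle had 0 genes tested.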
